A study of Mus musculus with 16 samples.

How the data were processed

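RNA sequencing was done on 16 libraries of the mouse macrophage line RAW264.7, 4 libraries in each of 4 groups: vehicle control, oxidised low-density lipoprotein (oxLDL) at 50 µg/ml, tirzepatide at 100 nmol/ml as the labels state it (nmol/l may be meant, which the data do not settle), and oxLDL with tirzepatide. Tirzepatide is a peptide drug that activates the receptors of the incretin hormones GIP and GLP-1. The labels give no duration of treatment and do not say whether the numbered libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

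The deposited table holds an expected count per gene and library, which the authors estimated with RSEM and did not scale between libraries. It also holds TPM, the transcript abundance scaled for length and depth, per gene and library as deposited by the authors, for the same 21965 genes. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, StringTie 1.3.1 and RSEM without a version, and the builds GRCm39 and mm39, but no annotation release. The annotation at hand was for the earlier mouse build, so no coordinates are given, and genes carry the symbols and Ensembl identifiers of the deposited table. A symbol shared by more than 1 identifier was kept apart by its identifier.

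Library totals ran from 15877278 to 17336019 counts, and 12954 to 13276 genes had a count above 0 in a library. Replicates differed by more than counting error: the chi-square per degree of freedom between replicates of a group, over genes with a summed count of at least 20, ran from 2.69 to 17.8 over 24 pairs of libraries, and the lowest Pearson correlation of log2 CPM across genes was 0.984. The biological coefficient of variation estimated by edgeR was 0.0633. Intervals for shares of counts in single libraries are 95% Wilson intervals and cover counting error only, since the reads carry no molecular identifiers.

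Expected counts were rounded and tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with its minimum count of 10, which left 11319 genes, TMM normalization, and quasi-likelihood tests (glmQLFit and glmQLFTest) of contrasts in 1 fit of all 16 libraries with a mean per group. Benjamini-Hochberg adjustment was done per contrast, and genes with an adjusted p under 0.05 were called, with no fold threshold. All adjusted p-values of genes below come from this test unless another is named. The contrasts were oxLDL, tirzepatide and the combination each against control, the combination against each single treatment, and the interaction, that is, whether the combination departed from the sum of the single effects on the log2 scale. The fit was tested on simulated data with 200 genes changed: between 41.8% and 47.8% of 1.2-fold changes and between 83.3% and 89.4% of 2-fold changes were recovered in the 3 main contrasts, with 5.33% to 6.21% false calls. These simulated counts held no structure of the libraries shared across genes, so recovery and false calls in the real data may be worse.

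The groups, the tests, 37 gene lists, the rule for named genes and the main alternatives were chosen before the data were examined. Lists with at least 4 tested members, 30 of the 37, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Each list was tested again with an estimated correlation and with the rotation test fry. Members were also counted with p-values adjusted over the list alone. The rule named, for the 3 main comparisons (each single treatment against control, and the combination against oxLDL), up to 8 called genes each way with the largest log2 changes, a mean of at least 5 TPM in the higher group and no overlap between the groups, up to 3 called members of each list, and 16 fixed genes of inflammation and lipid handling whether called or not. For the other contrasts it named the 5 genes with the smallest p, and not every gene under the rule is printed. Of the genes it named, 3 are not reported here. Enrichment of the table's own KEGG pathway annotation among called genes, chosen after the table was seen, used one-sided Fisher's exact tests of 314 pathways against the 4800 tested genes with an annotation. These tests take genes as independent, so their p-values do not measure the spread between libraries.

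Alternatives were the replicate number as a block, only the groups compared in the fit, DESeq2 size factors, quantile normalization with limma, no filter on low counts, a filter of 5 TPM in at least 4 libraries, DESeq2 1.42.0, and each library left out in turn. Alternatives chosen after the data were seen were leaving out controls 1 and 2 together, leaving out the libraries numbered 1 together, leaving out pancreatic acinar genes, and a covariate for the mitochondrial or for the acinar share of counts. Marker lists of pancreatic acinar, islet, hepatocyte, enterocyte, erythroid and muscle cells and a list of glucose-responsive targets of MondoA and ChREBP were also written after the first look at the data, before they were tested. The overlap between the oxLDL and tirzepatide responses, which share the controls, was compared with 20 simulated data sets without effects and with the 6 divisions of the controls into 2 and 2. No library was left out of the reported values, and no count or TPM column was left unused.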

Results

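Gene expression was measured by RNA sequencing in RAW264.7 cells, a mouse macrophage line, under vehicle, oxLDL, tirzepatide or their combination, with 4 libraries per group. Library totals were 16134421 to 16840886 counts in the controls and 15877278 to 17336019 in the treated libraries, and 11319 genes were tested. The question of the series is what tirzepatide does to polarization, inflammation and genes of atherosclerosis in macrophages given oxLDL.

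OxLDL, the modified lipoprotein that macrophages take up as they turn into foam cells, was first compared with vehicle. Transcripts of several inflammatory mediators rose. Il1b, which encodes interleukin-1 beta, went from 1.29 ± 0.658 TPM (SD, n = 4) in control to 16.4 ± 2.07 TPM with oxLDL, a log2 change of 3.64 (SE 0.41, adjusted p = 7.61e-06 by edgeR). Csf3, the granulocyte colony-stimulating factor, rose from 0.852 ± 0.39 to 8.29 ± 0.961 TPM, and Ptgs2, the inducible cyclooxygenase, from 76.2 ± 6.84 to 213 ± 14.4 TPM. Tnf fell from 163 ± 3.47 to 117 ± 5.39 TPM (log2 change -0.48, SE 0.07, adjusted p = 4.8e-05 by edgeR). Ccl5, a T-cell attracting chemokine, fell from 25.2 ± 0.511 to 10.9 ± 1.84 TPM. Nos2, the inducible nitric oxide synthase, fell as well (log2 change -0.45, SE 0.09). Il6 had a log2 change of 0.66 (SE 0.38, adjusted p = 0.383 by edgeR) and Ccl2 one of -0.70 (SE 0.25, adjusted p = 0.111 by edgeR), which did not pass, although Ccl2 did without a filter on low counts (0.0494).

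Genes of lipid storage, oxidative stress and lysosomes rose with oxLDL. Plin2, which coats lipid droplets, rose from 341 ± 25.3 to 711 ± 14.4 TPM (log2 change 1.03, SE 0.08, adjusted p = 6.75e-09 by edgeR), together with Hilpda (log2 change 1.17, SE 0.17) and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation (0.57, SE 0.07). Of 19 tested PPAR targets and lipid droplet genes 5 rose and 0 fell, or 6 and 1 when adjusted over the list alone. Of 28 NRF2 targets of the oxidative stress response 14 rose and 0 fell, 17 when adjusted over the list alone. Among them were Hmox1, heme oxygenase 1 (0.78, SE 0.10), the cystine transporter Slc7a11 (0.70, SE 0.07) and the pentose phosphate enzymes G6pdx (0.37, SE 0.05) and Pgd (0.38, SE 0.04). Of 39 lysosome and autophagy genes 14 rose and 0 fell, 20 when adjusted over the list alone, with Gla at 0.54 (SE 0.08). Of 17 foam cell genes 8 rose, including Ctsl (0.28, SE 0.06), and of 19 macrophage lineage genes 5 rose, including Cd14 (0.73, SE 0.11) and Lyz1 (0.73, SE 0.07). When adjusted over the list alone these were 10 higher with 2 lower and 6 higher. All 5 lists passed camera and passed again with an estimated correlation (adjusted p = 0.00249 for 4 of them and 0.0261 for lysosome and autophagy).

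Interferon-stimulated genes fell as a group with oxLDL. Of 29 tested members 14 fell and 0 rose, 20 when adjusted over the list alone, with a median log2 change of -0.46 (camera adjusted p = 1.48e-22, and adjusted p = 0.00249 with an estimated correlation). Examples were Rtp4 (-0.89, SE 0.145), Ifih1, an RNA sensor (-0.72, SE 0.09), Ifi44 (-0.71, SE 0.10) and Usp18 (-0.52, SE 0.07). Antigen presentation genes also fell as a list, 3 of 18 by themselves and 4 when adjusted over the list alone, with B2m at -0.41 (SE 0.05) and an adjusted p = 0.0261 with an estimated correlation. Some genes of cholesterol export and lipid synthesis were lower. Abca1, the cholesterol exporter, fell from 158 ± 8.41 to 111 ± 5.12 TPM (log2 change -0.52, SE 0.06). Its relative Abcg1 (-0.51, SE 0.08) and the desaturase Scd2 (-0.70, SE 0.09) fell too. Of 23 LXR targets and cholesterol efflux genes 2 rose and 6 fell, 5 and 9 when adjusted over the list alone. The list's call (camera adjusted p = 0.0172) was lost with an estimated correlation (adjusted p = 0.226 with an estimated correlation) and without control 3, control 4 or oxLDL 1 (adjusted p = 0.0514, 0.0588 and 0.0506 by camera). The 16 fatty acid synthesis genes, 3 of them lower and 1 higher with 6 lower when adjusted over the list alone, passed camera at 0.000549, with adjusted p = 0.178 with an estimated correlation.

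The polarization lists did not move one way with oxLDL. Of 17 tested markers of classical (M1) activation 3 rose and 3 fell, both over all genes and when adjusted over the list alone. Their median log2 change was -0.05, their mean 0.26 and the direction of the camera test upward (adjusted p = 0.575 by camera). Of 9 tested markers of alternative (M2) activation 1 fell, and 2 rose and 2 fell when adjusted over the list alone (adjusted p = 0.444 by camera). Of 23 inflammatory cytokines and chemokines 5 rose and 6 fell, 6 and 7 when adjusted over the list alone, with a median of -0.07, a mean of 0.24 and a downward test (adjusted p = 0.948 by camera). Arg1 and Mrc1, the textbook M2 markers, and the scavenger receptor Cd36 were too low to test, with at most 4, 2 and 9 counts summed over the 4 libraries of a group, while Msr1, another scavenger receptor, rose (log2 change 0.34, SE 0.07).

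**Figure D1:**
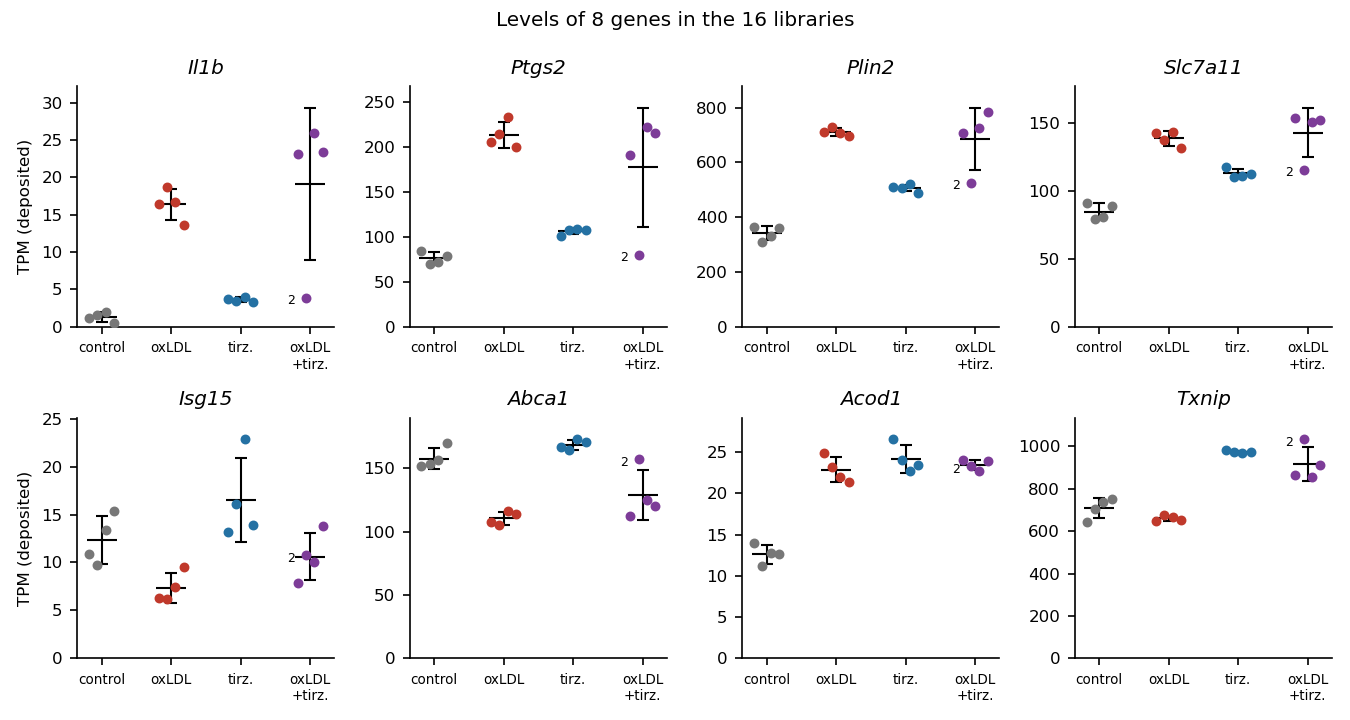
Deposited TPM of 8 genes in each of the 16 libraries, by group; points are libraries, horizontal bars the mean and SD of 4 libraries, and the digit 2 marks library 2 of the combination group. Il1b lay at 13.7 to 18.7 TPM with oxLDL and at 0.457 to 2.00 TPM in control, and library 2 of the combination lay at 3.91 TPM.

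In all, 514 genes were called for oxLDL against control, 282 higher and 232 lower, and 2042 genes had an unadjusted p under 0.05 where chance gives 566. Of the 33 genes that fell more than 2-fold 20 were pancreatic acinar genes such as digestive enzymes, which were present in controls 1 and 2, while 14 genes rose more than 2-fold. KEGG pathways among the higher genes included Lysosome (18 of 120 members, 4.2 by chance, adjusted p = 1.93e-05 by Fisher's exact test), and the lower genes held Influenza A (16 of 119, 3.15 by chance), which lists interferon response genes, and Pancreatic secretion (14 of 54, 1.43 by chance). The count fell to 307 without control 2 and to 324 without oxLDL 1. It was 307 without controls 1 and 2, 813 with the mitochondrial share and 311 with the acinar share as a covariate.

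Tirzepatide alone was compared with vehicle next. Acod1, the macrophage enzyme that makes itaconate, rose from 12.6 ± 1.16 to 24.2 ± 1.69 TPM (SD, n = 4; log2 change 0.90, SE 0.08, adjusted p = 7.02e-07 by edgeR). The early response factor Klf10 (0.49, SE 0.05), Txnip, a regulator of glucose uptake (0.43, SE 0.05), and the lipid droplet gene Plin2 (0.53, SE 0.08) rose, each with all 4 treated libraries above all 4 controls. Lcn2, an iron-binding protein of innate immunity, rose from 353 ± 44.7 to 605 ± 41 TPM, and Csf3 from 0.852 ± 0.39 to 4.36 ± 0.703 TPM. Surface and immune genes that rose were Msr1 (0.44, SE 0.07), the integrin Itgam (0.36, SE 0.05), the complement factor Cfp (0.48, SE 0.07), Igsf6 (0.69, SE 0.12), the chemokine Cxcl2 (0.41, SE 0.09) and the inflammasome sensor Nlrp3 (0.34, SE 0.06). The small heat shock protein Cryab fell from 43.3 ± 10.4 to 20.6 ± 4.23 TPM (log2 change -1.14, SE 0.15). Immune and surface genes fell too: Adgre1, a macrophage surface marker (-0.22, SE 0.04), the cytokine Il15 (-0.67, SE 0.14), H2-K1 of antigen presentation (-0.29, SE 0.06) and Ccl5 (-0.64, SE 0.17, adjusted p = 0.0385 by edgeR). Il15 did not pass without control 2 (adjusted p = 0.062 by edgeR), H2-K1 not without control 2 or tirzepatide 1 or 2 (0.0736, 0.0557 and 0.0501), and Ccl5 not without any 1 of 7 libraries (0.0505 to 0.126).

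Several of the fixed inflammatory and lipid genes did not pass with tirzepatide alone. Il1b had a log2 change of 1.45 (SE 0.49, adjusted p = 0.0949 by edgeR), from 1.29 ± 0.658 to 3.65 ± 0.29 TPM, and passed in 4 other settings: without library 2 of the combination group in the fit (adjusted p = 0.00166 by edgeR), with only the 2 groups in the fit (0.0272), without a filter on low counts (0.00865) and by limma after quantile normalization (0.0248). Nos2 had -0.20 (SE 0.09, adjusted p = 0.222 by edgeR) and passed without control 1 (-0.29, adjusted p = 0.0257 by edgeR), without controls 1 and 2 (0.0407) and with the mitochondrial share as a covariate (0.0101). Tnf had -0.06 (SE 0.06), Il6 -0.04 (SE 0.40), Ccl2 0.23 (SE 0.23), Abca1 0.07 (SE 0.06), Abcg1 0.02 (SE 0.08) and Hmox1 0.06 (SE 0.10), with adjusted p-values by edgeR from 0.613 to 0.97. The direction of Il6 and Abcg1 turned in some settings.

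Of the 30 lists tested 10 passed camera for tirzepatide against control and none of the 10 passed with an estimated correlation. Of 40 cytosolic ribosomal protein genes 10 fell and 0 rose, 29 when adjusted over the list alone, with a median log2 change of -0.13. The list had camera adjusted p = 2.87e-17 and adjusted p = 0.141 with an estimated correlation. Of 40 cell cycle genes 9 rose and 0 fell, 12 when adjusted over the list alone, with the mitotic kinesin Kif20a at 0.35 (SE 0.07) and adjusted p = 0.122 with an estimated correlation. Of 25 ATF4 targets 2 rose, 3 when adjusted over the list alone, and 24 had a positive sign (adjusted p = 0.136 with an estimated correlation). Of 29 interferon-stimulated genes 3 rose, 4 when adjusted over the list alone (adjusted p = 0.365 with an estimated correlation, and 0.0763 by camera without tirzepatide 3). The M1 list passed upward, with 1 higher and 1 lower of 17, 4 and 1 when adjusted over the list alone (adjusted p = 0.122 with an estimated correlation), and the M2 list did not pass (0 of 9, 1 higher when adjusted over the list alone, camera adjusted p = 0.513). The KEGG pathway Ribosome held 29 of the lower genes among 127 members, against 2.83 by chance (adjusted p = 4.86e-20 by Fisher's exact test). Fisher's test takes genes as independent. Its p-value thus ignores the correlation between genes, with which the ribosomal protein list did not pass camera (adjusted p = 0.141 with an estimated correlation).

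In all, 462 genes were called for tirzepatide against control, 197 of them lower and the others higher, and 2100 genes had an unadjusted p under 0.05. Most changes were small: 5 genes rose and 17 fell more than 2-fold, and 7 of the 17 were pancreatic acinar genes. The count was 119 without control 2, 247 without control 3, and 186, 199 and 293 without tirzepatide 1, 2 or 3, and it was 264 with only these 2 groups in the fit. It was 204 without controls 1 and 2, 857 with the mitochondrial and 217 with the acinar share as a covariate, and 291 without the libraries numbered 1.

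**Figure D2:**
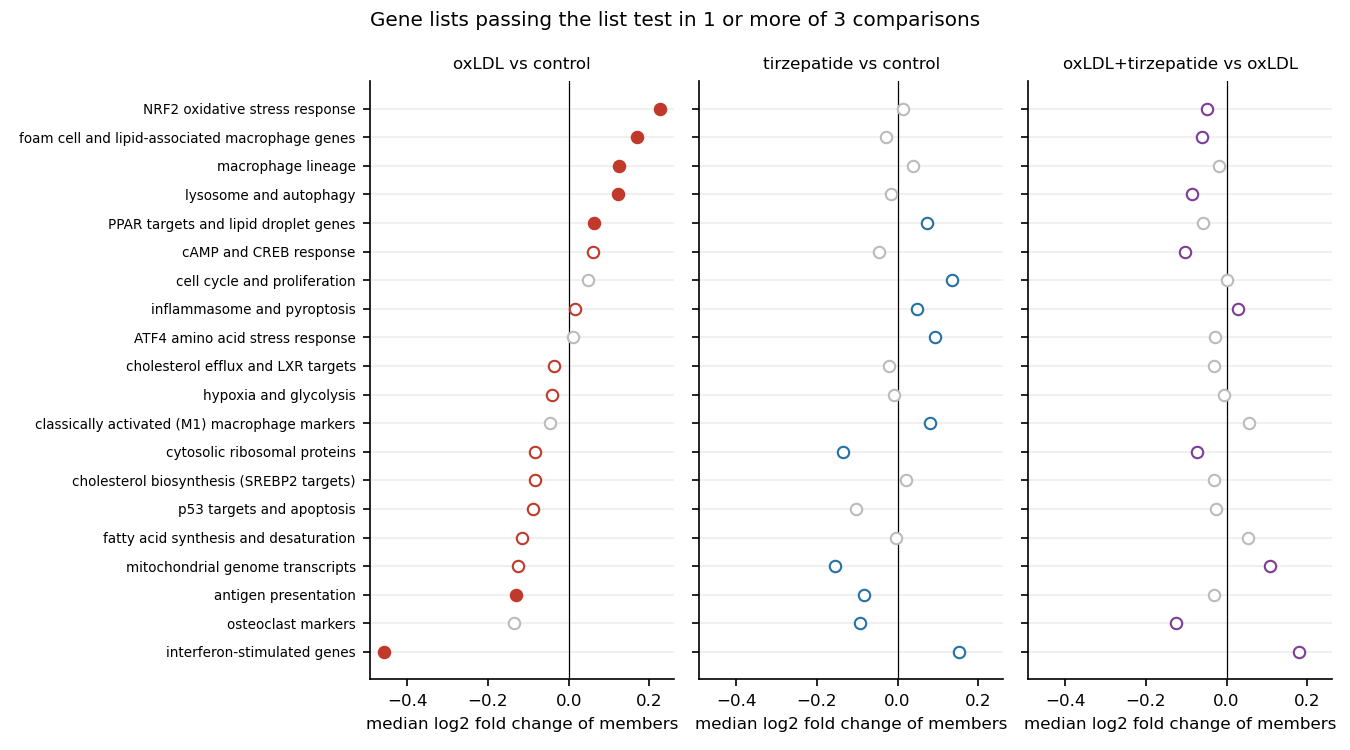
Median log2 change of the tested members of each gene list that passed camera in at least 1 of the 3 main comparisons; grey rings mark lists that did not pass, coloured rings those that passed only at the preset correlation of 0.01, and filled circles those that also passed with an estimated correlation. Interferon-stimulated genes had a median of -0.46 with oxLDL, 0.15 with tirzepatide and 0.18 with the combination against oxLDL.

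The combination against oxLDL alone addressed the question of the series title, what tirzepatide did in the presence of oxLDL. Klf10 rose from 56.3 ± 1.24 to 79.6 ± 4.66 TPM (SD, n = 4; log2 change 0.48, SE 0.05, adjusted p = 4.83e-06 by edgeR), and Txnip from 661 ± 11.3 to 917 ± 81.4 TPM (0.47, SE 0.05, adjusted p = 4.83e-06 by edgeR), each with all 4 combination libraries above all 4 oxLDL libraries. Arrdc4, an arrestin-domain gene related to Txnip, rose by 0.43 (SE 0.07, adjusted p = 0.011 by edgeR), and Ints6l by 0.28 (SE 0.05, adjusted p = 0.0369 by edgeR). These 4, all higher, were the only genes called in this fit, whereas DESeq2 called 12 higher and 9 lower. The same 3 genes Klf10, Txnip and Arrdc4 rose with tirzepatide alone, Arrdc4 by 0.31 (SE 0.07), a value looked up after its change beside oxLDL was seen.

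None of the following fixed genes passed in the combination against oxLDL. Il1b had a log2 change of 0.21 (SE 0.29, adjusted p = 0.837 by edgeR), with 16.4 ± 2.07 TPM under oxLDL and 19.1 ± 10.2 TPM under the combination. Its mean under the combination was pulled down by library 2 at 3.91 TPM. The other combination libraries lay at 23.2 to 25.9 TPM, above all oxLDL libraries at 13.7 to 18.7 TPM. Tnf had 0.08 (SE 0.07), Il6 -0.14 (SE 0.36), Nos2 -0.10 (SE 0.09), Ccl2 0.37 (SE 0.25), Msr1 0.17 (SE 0.07), Abca1 0.21 (SE 0.06), Abcg1 0.10 (SE 0.08) and Hmox1 -0.15 (SE 0.09), with adjusted p-values by edgeR from 0.303 to 0.923. Tnf and Abcg1 were -0.03 and -0.05 without library 2 of the combination, Il6 was 0.08 without oxLDL 4, and Il1b was -0.06 under quantile normalization. Egr1, an early response gene, had -0.42 (SE 0.08, adjusted p = 0.0847 by edgeR) and passed without control 1 (0.0443) and without library 3 of the combination (0.0343), as well as with DESeq2 (0.0112) and without a filter on low counts (0.0195).

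Of the 30 lists 9 passed camera for the combination against oxLDL and none of the 9 passed with an estimated correlation. Of 29 interferon-stimulated genes 0 were called, 3 rose when adjusted over the list alone, and 27 had a positive sign (camera adjusted p = 6.76e-09, adjusted p = 0.113 with an estimated correlation). Of 39 lysosome and autophagy genes 0 were called, 2 fell when adjusted over the list alone and 4 had a positive sign (camera adjusted p = 6.76e-09, adjusted p = 0.113 with an estimated correlation). The foam cell list had 0 of 17 called and 3 lower when adjusted over the list alone (adjusted p = 0.113 with an estimated correlation), and the NRF2 list 0 of 28 by either count (adjusted p = 0.345 with an estimated correlation). Without library 2 of the combination the NRF2 list no longer passed camera (adjusted p = 0.595), nor did it without oxLDL 2 (0.0588). Library 2 of the combination, which carried less of the oxLDL response, added to the other shifts. Without it the median log2 change of the interferon list was 0.13 in place of 0.18, with 1 gene higher when adjusted over the list alone and 24 of positive sign. That of the lysosome list was -0.06 in place of -0.09, with 0 lower and 5 of positive sign, and the foam cell list had 2 lower. These 3 lists still passed camera. The M1 and M2 lists had 0 of 17 and 0 of 9 called by either count (camera adjusted p = 0.345 and 0.259).

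The count of 4 genes stood beside 1146 genes with an unadjusted p under 0.05, where chance gives 566. DESeq2 called 21 genes (12 higher, 9 lower), edgeR without a filter on low counts 32 (17 and 15), edgeR with only the 2 groups in the fit 7 (5 and 2), and limma after quantile normalization 5 (4 and 1). Leaving out a library gave 2 genes without oxLDL 2, 3 or 4, 7 without library 1 of the combination and 8 without control 1, while leaving out controls 1 and 2 gave 8 and the libraries numbered 1 gave 13. Klf10 and Txnip were called in each of these settings, whereas Arrdc4 was lost without oxLDL 2, 3 or 4 or library 2 of the combination (adjusted p = 0.0744, 0.117, 0.0661 and 0.0525 by edgeR) and Ints6l without any of 12 of the 16 libraries (adjusted p from 0.0534 to 0.167 by edgeR).

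Library 2 of the combination group carried less of the oxLDL response than the other 3. Its Il1b stood at 3.91 TPM against 23.2 to 25.9 TPM in the others and 3.38 to 4.03 TPM with tirzepatide alone, its Plin2 at 524 TPM against 708 to 785 TPM, and its Slc7a11 at 116 TPM against 151 to 153 TPM. On a scale from 0 at the mean of the tirzepatide libraries to 1 at the mean of the other 3 combination libraries, the 282 genes raised by oxLDL stood at -0.0535 in this library, within the range of the tirzepatide libraries from -0.0881 to 0.0614. The 212 genes that oxLDL lowered, pancreatic acinar genes left out, stood at 0.303, above the tirzepatide libraries at -0.142 to 0.0888. Without it, 3 genes were called for the combination against oxLDL, 2 of them among the 4, and 444 in place of 174 for the combination against tirzepatide.

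**Figure D3:**
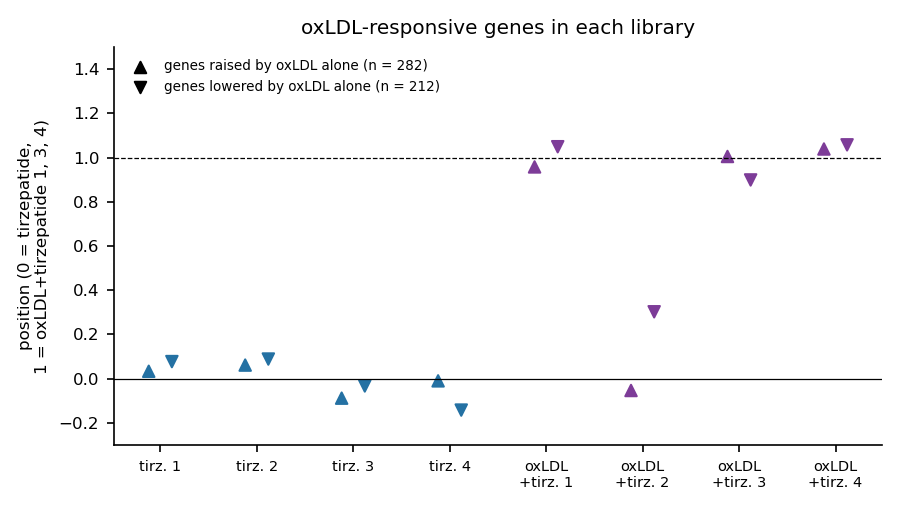
Mean position of the 282 genes raised and the 212 genes lowered by oxLDL alone, in each library given tirzepatide, on a scale from 0 (mean of the 4 tirzepatide libraries) to 1 (mean of combination libraries 1, 3 and 4). Library 2 of the combination lay at -0.0535 and 0.303, and the other 3 combination libraries between 0.899 and 1.06.

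Whether tirzepatide moved the oxLDL response back toward control was asked of the 514 genes called for oxLDL. In the combination against oxLDL 1 of them, Ints6l, was called in the opposite direction and 0 in the same direction. Of the 514, 68.1% had the opposite sign, with a median change along the oxLDL direction of -0.06 on the log2 scale. As the oxLDL libraries enter both contrasts, some return is built in: 20 simulated data sets without any effect of tirzepatide beside oxLDL gave 66.8% to 72.5%. These had 1197 to 1326 genes called for oxLDL in place of 514, so they do not match the data in that respect. With genes chosen in 2 oxLDL libraries and measured against the other 2 the share was 67.5% (53.8% to 78.2% over 6 divisions), and without library 2 of the combination it was 48.7% (40.1% to 53.8%).

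The oxLDL and tirzepatide responses overlapped. Of the genes called in both comparisons with control 82 rose in both, 51 fell in both and 2 went opposite ways, against 6.6, 4.04 and 10.3 if the calls were independent. Plin2, Acod1, Csf3, Msr1, Nlrp3 and G6pdx rose in both, and Cryab fell in both. The 4 controls enter both comparisons, which alone makes the log2 changes correlate. Their Pearson correlation was 0.599 over all genes and 0.493 without the acinar genes, and simulated data without effects gave 0.509 and 0.506 on average. With the controls divided 2 and 2 between the comparisons it was 0.225 and 0.123 on average, and 16 to 39 genes were shared in the same direction (mean 26.0). Of these, 15.7 rose and 10.3 fell in both on average, against 1.57 and 1.09 if the calls were independent. The 133 genes shared in the same direction were 36 without control 2, and 68, 78 and 87 without oxLDL 1, 2 or 4, and 68 and 71 without tirzepatide 1 or 2. They were 50 without controls 1 and 2, 281 with the mitochondrial and 55 with the acinar share as a covariate, and 69 without the libraries numbered 1.

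The effect of oxLDL on top of tirzepatide was read from the combination against tirzepatide. Il1b rose by 2.39 on the log2 scale (SE 0.35, adjusted p = 0.00105 by edgeR, n = 4 per group), and Clec4e, a C-type lectin receptor, from 21.1 ± 1.5 to 35.1 ± 7.93 TPM. Acy1, an aminoacylase, fell from 4.07 ± 0.537 to 1.04 ± 0.273 TPM, and Cpd, a carboxypeptidase, from 60.9 ± 1.82 to 45.9 ± 2.75 TPM, as did the interferon-inducible Ifi203 (-0.51, SE 0.08). Interferon-stimulated genes fell as a list, 8 of 29 by themselves and 18 when adjusted over the list alone, and it was the only one of 16 passing lists that passed with an estimated correlation (adjusted p = 0.0135 with an estimated correlation). In all, 174 genes were called, 86 higher and 88 lower. The count was 58 to 102 without combination 4, 1 or 3 or tirzepatide 4, 3 or 2 (58, 64, 93, 94, 98 and 102), and 444 without combination 2. DESeq2 called 308 genes, edgeR without a filter 282, with only the 2 groups 107, and without the libraries numbered 1 86.

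The combination was also compared with vehicle. Plin2 rose by 0.97 on the log2 scale (SE 0.08, adjusted p = 2.48e-08 by edgeR, n = 4 per group), Acod1 by 0.88 (SE 0.08), Slc7a11 by 0.74 (SE 0.07), Klf10 by 0.57 (SE 0.05) and G6pdx by 0.43 (SE 0.05). Of 28 NRF2 genes 12 rose and 0 fell, 13 when adjusted over the list alone, of 18 antigen presentation genes 7 fell by either count, and of 19 PPAR targets and lipid droplet genes 5 rose, 6 with 2 lower when adjusted over the list alone. These lists passed with an estimated correlation (adjusted p = 0.0326, 0.0329 and 0.0329). Of 40 ribosomal protein genes 22 fell, 32 when adjusted over the list alone (adjusted p = 0.0871 with an estimated correlation). In all, 1012 genes were called, 531 higher and 481 lower, 41 of them more than 2-fold lower with 20 acinar genes among these. Of the alternatives, 475 were called without control 2, 506 without control 3, 526 and 627 without combination 1 or 4, 410 with only the 2 groups and 1601 with the mitochondrial share as a covariate.

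The interaction asked whether the combination departed from the sum of the single effects. Acod1 rose by 0.85 with oxLDL, by 0.90 with tirzepatide and by 0.88 with both, a departure of -0.87 (SE 0.11, adjusted p = 0.000704 by edgeR, n = 4 per group), with 22.9 ± 1.52, 24.2 ± 1.69 and 23.5 ± 0.622 TPM in the 3 treated groups and 12.6 ± 1.16 TPM in control. Plin2 departed by -0.59 (SE 0.11) and Cxcl2 by -0.70 (SE 0.12). The combination libraries were split in Cxcl2. Libraries 1 and 2 stood at 209 and 196 TPM, near the controls at 200 to 213 TPM. Libraries 3 and 4 stood at 290 and 300 TPM, within the oxLDL range of 270 to 321 TPM. Sema3e, a semaphorin, departed by -0.40 (SE 0.07), and the secreted glycoprotein gene Stc1, which fell with either treatment, by 0.53 (SE 0.09). In all, 8 genes passed, 3 above and 5 below the sum, with 1168 genes at an unadjusted p under 0.05 and 58 genes by DESeq2. Plin2 and Cxcl2 did not pass without tirzepatide 2 (adjusted p = 0.0576 by edgeR for both) or 3 (0.0675 and 0.051), Stc1 not without tirzepatide 3 (0.0675), Plin2 not without oxLDL 1 (0.0771) and Cxcl2 not without combination 1 (0.051). Only Acod1 was called without control 2, oxLDL 2, oxLDL 3 or tirzepatide 1, while 3 genes were called without tirzepatide 3, 4 without oxLDL 1, 5 without combination 1, 15 without control 1 and 16 without control 4.

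The receptors of tirzepatide were read from their own transcripts. Glp1r had 5 counts in total, in 3 of the 16 libraries, and was not tested. Gipr had 37 to 70 counts per library, 2.48 ± 0.574 TPM (SD, n = 16), and its log2 changes were -0.20 (SE 0.22) with oxLDL, -0.34 (SE 0.22) with tirzepatide and 0.21 (SE 0.22) for the combination against oxLDL, none of which passed. Of the 25 tested cAMP and CREB response genes, the pathway downstream of these receptors, 0 were called with tirzepatide alone by either count (camera adjusted p = 0.413). Beside oxLDL 0 were called, 2 rose and 1 fell when adjusted over the list alone, and the list passed camera downward at 0.0126, with adjusted p = 0.345 with an estimated correlation and 0.0727, 0.0655 and 0.204 by camera without oxLDL 3, combination 1 or combination 2.

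**Figure D4:**
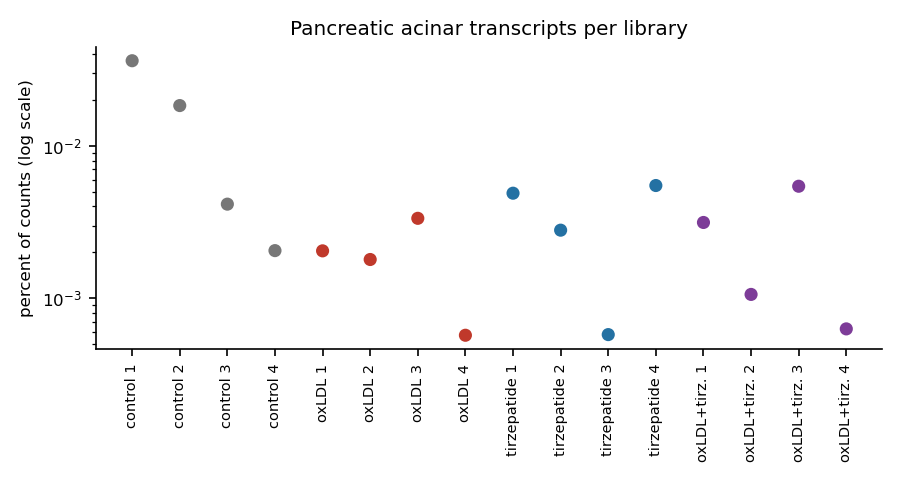
Share of counts from pancreatic acinar genes in each of the 16 libraries, as percent on a log axis. Controls 1 and 2 lay at 0.0361% and 0.0184%, and the 12 treated libraries between 0.000572% and 0.00549%.

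Pancreatic acinar transcripts were present in the controls at 0.0361% of counts in control 1 (95% Wilson interval 0.0352 to 0.0371%), 0.0184% in control 2 (0.0177 to 0.019%), 0.00414% in control 3 (0.00385 to 0.00446%) and 0.00205% in control 4 (0.00185 to 0.00229%). Of the 23 acinar genes tested 20 were called lower with oxLDL, 7 with tirzepatide and 20 with the combination, each against control, and 0 in the other contrasts. Clu, which is not on the acinar list, fell by 1.87 on the log2 scale with oxLDL (SE 0.41) and had -0.75 (adjusted p = 0.313 by edgeR) without controls 1 and 2. Markers of other cell types were scarce: of the lists of dendritic cells, neutrophils, lymphocytes, fibroblasts and epithelial or endothelial cells 2, 3, 2, 3 and 4 genes could be tested, and with either single treatment 1 of these was called, the neutrophil marker Lcn2, higher with tirzepatide.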

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

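The tests of library 2 of the combination group, the tests of acinar RNA and of a treatment effect on acinar genes, and the test whether library 2 hides an effect were chosen only after the results were seen.

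Library 2 of the combination lay apart from the other 3 libraries of its group in several genes. In 5 of the genes examined its Dixon's ratio, the gap to the nearest library over the range of the 4, passed the value that chance passes in 1 of 20 groups. Its TPM in these was 3.91 for Il1b (others 23.2 to 25.9), 116 for the cystine transporter Slc7a11 (151 to 153), 208 for lysozyme Lyz1 (251 to 253), 228 for the desaturase Scd2 (144 to 150) and 4.58 for the signalling adaptor Traf5 (3.17 to 3.25). Other genes were also far apart, such as Ptgs2 at 79.9 TPM (191 to 222), Fos at 8.45 (24.8 to 33.9), Crem at 11.96 (27.4 to 31.5) and Hmox1 at 425 (668 to 740). A mislabelled tirzepatide library should lie within the tirzepatide range for raised and for lowered genes. It did so for raised genes, at -0.0535, but for the genes that oxLDL lowered it lay at 0.303, above the highest tirzepatide library at 0.0888, which argues against that account, although only 4 libraries give this range. Its total of 16880487 counts lay within the 15877278 to 17336019 of the other 15 libraries, which argues against library size. Its mitochondrial share of 9.37% lay within their 7.69% to 11.2%. RNA quality itself was not measured, so this share cannot exclude it. A weaker oxLDL exposure or response in 1 culture stays open: the library lay at least 0.596 below the lowest of the other 3 in both gene sets, but this restates the pattern and does not favour that account over others. A sample mixed in part with a tirzepatide sample was not tested.

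Pancreatic acinar transcripts in the controls were the second pattern. Across the 38 acinar genes with a count, controls 1 and 2 had a Spearman correlation of 0.973 (genes are not independent replicates), as RNA from 1 foreign source could give. Control 1 correlated at 0.926 with control 3 and at 0.644 with tirzepatide 4, the treated library with the highest share, so 1 source for all libraries is not shown. A different source is not shown either. Counts were allotted differently among amylase genes, with Amy2a2 at 614 and 7.13 and Amy2a5 at 1.01 and 188 in control 1 and tirzepatide 4. Other acinar genes had few counts in tirzepatide 4, and how far this lowers the correlation was not tested. Ctrb1, which encodes chymotrypsinogen, had 548 and 355 counts in controls 1 and 2 against 56 and 27 in controls 3 and 4. A treatment effect on the macrophages should part all controls from all treated libraries, but 2 controls lay within the range of the 12 treated libraries. A wider mixture of tissues is argued against by 5 further marker lists, of which 1, that of pancreatic islets with 5 counts, was highest in control 1. Hepatocyte, enterocyte, erythroid and muscle markers summed to 41, 369, 2 and 10 counts in control 1 and to at most 65.0, 566, 8 and 12 in any library. RNA from acinar cells may have entered at any step before sequencing, or been assigned by an index error, which was not tested.

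Many genes were called for tirzepatide without oxLDL and few with it, the third pattern. Without library 2 of the combination 3 genes were called, which argues against that library alone hiding the effect. Over all genes library 1 of the combination also lay apart. Its chi-square per degree of freedom against the others of its group was 10.9 to 11.1, and that between libraries 3 and 4 was 3.08. Leaving out libraries 1 and 2 together was not run, so spread within the group may still hide changes. Structure among the controls as the whole account is argued against by the 76.3% of tirzepatide genes outside the acinar list that moved the same way in the combination against oxLDL, a comparison without controls, where the highest of the other splits gave 73.6%. With genes chosen in 2 control and 2 tirzepatide libraries, the mean change beside oxLDL was 31.9% of that in held-out libraries without it. Both the choice and the held-out change use controls, whereas the change beside oxLDL uses none. A shift shared by the controls could therefore lower this share too. The share cannot tell such a shift from a smaller tirzepatide effect beside oxLDL. The difference itself, tested as the interaction, passed for 8 genes.

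The interaction set 8 genes apart, each tested by edgeR as a departure of the combination from the sum of the single effects. Acod1 departed by -0.87 (adjusted p = 0.000704), Plin2 by -0.59, Cxcl2 by -0.70, Sema3e by -0.40 and Stc1 by 0.53 on the log2 scale (adjusted p = 0.0221 for each of these 4). Nlrp3 departed by -0.42 (adjusted p = 0.0356), Dixdc1 by 0.47 (0.0347) and the acetylcholine receptor gene Chrnb1 by 0.84 (0.0267), and these 3 were named after their values were seen. Only Acod1 kept its call without control 2, oxLDL 2, oxLDL 3 or tirzepatide 1, where the adjusted p of Sema3e was 0.0741, 0.0668, 0.0639 and 0.0701.

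Further single libraries lay apart from the other 3 of their group by the same ratio. With tirzepatide these were Ptgs2 at 101 TPM in library 1 (others 108 in each case), the transcription factor Crem at 16.5 TPM in library 3 (13.5 to 13.7), and in library 4 Scd2 at 272 TPM (232 to 236), Nos2 at 74.8 TPM (60.9 to 61.6) and Il6 at 3.17 TPM (0.993 to 1.31). With oxLDL, library 4 had 222 TPM of Lyz1 (256 to 262) and 44.3 TPM of Clec4e (33.6 to 35.2). Among controls, Egr1 stood at 8.32 TPM in control 1 (9.78 to 10.0) and Cpd at 58.1 TPM in control 4 (51.9 to 52.8). In all 14 of 272 groups of 4 values held such a library, and chance gives 13.6, while 5 of the 14 fell in library 2 of the combination.

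Whether chance groupings of the libraries call as many genes was tested for each contrast, with only the groups compared in the fit where these are 2. Only the real grouping reached its count for oxLDL against control (1 of 35 splits, 516 genes, highest other 5). The same held for the combination against tirzepatide (1 of 35, 107 genes, highest other 12). It held too for the combination against control (1 of 35, 410 genes, highest other 44, with control 1 and library 2 of the combination exchanged). These counts make chance an unlikely account without excluding it. A share of 1 of 35 (2.86%) is the smallest that 35 splits can give, and it was not adjusted over the contrasts. For tirzepatide against control the real grouping also called the most genes (1 of 35, 264 genes). The split that exchanged control 1 and tirzepatide 4 called 203 genes, so the count does not exclude chance. Those 203 genes point to a structure of the samples besides the treatment. Chance cannot be excluded for the combination against oxLDL either (2 of 35, 7 genes, highest other 8). The split with 8 genes set libraries 1 and 2 of both groups against libraries 3 and 4. It may thus reflect a step shared by library number, which was not tested. For the interaction the labels of all groups were shuffled over the libraries. Of 100 such assignments 2, the real one included, called as many as the real 8 genes, and the highest other called 33. Shuffling also breaks up the effects of oxLDL and of tirzepatide, which adds to the spread within the shuffled groups. These draws therefore cannot exclude chance for the interaction.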

How the results depend on the processing

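The alternatives that left out controls 1 and 2, the libraries numbered 1 or the acinar genes, that used the mitochondrial or acinar share as a covariate, and that left library 2 of the combination out of the list tests and of the moved-back share were chosen only after the data were seen.

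Of 162 results for named genes 139 were called, and 81 of these kept their call and direction in every alternative run. DESeq2 size factors and leaving out acinar genes changed 0 of the 162, DESeq2 changed the side of the threshold for 1 weaker and 1 stronger result, and leaving out control 2 kept 118. Of 72 list calls 14 held with an estimated correlation, 52 with fry, 46 with quantile normalization and 51 without a filter on low counts.

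The numbers of the libraries were not taken to pair them: 5 of 20 correlations between libraries of 1 number exceeded 0.1, from -0.13 to 0.19, and 6 of 16 libraries correlated best with their own number. The mitochondrial share did follow the numbers, being higher in libraries 1 and 2 than in libraries 3 and 4 of every group, by at least 0.443 to 1.14 percentage points. Chance gives such an order for any 2 numbers with a probability of 0.00463, a check chosen after the values were seen, so a step shared by number is not excluded. The second principal component of log2 CPM (11.8% of the variance) fell with each number in control (14.6 to -11.9), oxLDL (7.06 to -0.61) and tirzepatide (-2.66 to -13.6). Combination libraries 1 to 4 did not keep this order (18.5, -6.11, 8.29 and 3.11). The main fit held no term for the number. With the number as a block, 750 genes were called for tirzepatide against control, 17 for the combination against oxLDL, 378 for it against tirzepatide and 29 for the interaction, and the overlap was 210 genes; all main calls were among these 4 counts. Egr1 passed in the combination against oxLDL (adjusted p = 0.0395).

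With only the groups compared in the fit, 264 genes were called for tirzepatide, 7 for the combination against oxLDL, 107 for it against tirzepatide and 410 for it against control; the construction leaves fewer samples to estimate the spread. Without a filter on low counts, the combination gave 32 genes against oxLDL and 282 against tirzepatide, and the interaction 39. DESeq2 gave 21, 308 and 58. The cause was not tested.

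Without controls 1 and 2, 307 genes were called for oxLDL, 204 for tirzepatide, 8 for the combination against oxLDL and 5 for the interaction, with an overlap of 50. With the mitochondrial share as a covariate the counts were 813 for oxLDL, 857 for tirzepatide, 1601 for the combination against control and 14 for the interaction, with an overlap of 281. With the acinar share they were 311, 217 and, for the interaction, 5, with an overlap of 55. Without the libraries numbered 1 they were 291 for tirzepatide, 13 for the combination against oxLDL, 86 against tirzepatide and 4 for the interaction, with an overlap of 69. With the controls divided 2 and 2 the overlap was 26.0 on average. The cause was not tested beyond the fewer samples in some of these.

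Leaving out 1 library at a time gave 307 to 594 genes for oxLDL, 119 to 542 for tirzepatide, 2 to 8 for the combination against oxLDL, 58 to 444 against tirzepatide, 475 to 1450 against control and 1 to 16 for the interaction. The lowest count came without control 2 for both single treatments (307 and 119) and for the combination against control (475). The overlap ran from 36 to 179 genes and the share of oxLDL genes with the opposite sign from 56.8% to 74.7%. With the oxLDL libraries split and without library 2 of the combination that share was 48.7%, on the other side of an even share.

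Signs turned only in genes that were not called. For tirzepatide against control, Il6 ran from -0.68 to 0.13 without single libraries and was 0.0237 with the acinar share and 0.13 without the libraries numbered 1. Abcg1 ran from -0.0157 to 0.0401, and was -0.0137 with quantile normalization, -0.0226 without controls 1 and 2, -0.00672 and -0.0197 with the mitochondrial and acinar share, and -0.00352 without the libraries numbered 1. For the combination against oxLDL, Il1b was -0.0608 with quantile normalization, and without single libraries Il6 ran from -0.373 to 0.0805, Tnf from -0.0266 to 0.127 and Abcg1 from -0.0542 to 0.165. The adjusted p of these turned values was above 0.7, and the cause was not tested.

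The list of mitochondrial genome transcripts turned its direction. Its adjusted p by camera ran from 0.000972 to 0.627 for oxLDL and from 0.000289 to 0.952 for tirzepatide without single libraries, with the turn without control 1 (0.627 and 0.952). For oxLDL it was 0.0393 without controls 1 and 2, 0.0509 with the mitochondrial and 0.545 with the acinar share; for tirzepatide 0.114 without controls 1 and 2 and 0.0101 with the mitochondrial share; for the interaction 0.125 with the mitochondrial share. The mitochondrial share, 11.2% in control 1, is itself the sum of these transcripts.

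Alternatives for TPM as the tested unit and library weights were not run, since counts were tested, and no DESeq2 version of the list tests was run. At this depth 41.8% to 47.8% of simulated 1.2-fold changes were recovered, so changes of that size are often missed. The simulated libraries had no structure shared across genes, so the share missed in the real data may be larger.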

Other observations

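The test of glucose-responsive targets was chosen only after Txnip, Arrdc4 and Klf10 were seen, but before its result.

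Further groups of genes passed camera with oxLDL but not with an estimated correlation. Of 14 inflammasome genes 3 rose by either count (adjusted p = 0.226 with an estimated correlation), and of 24 p53 targets 2 fell, with 2 higher and 2 lower when adjusted over the list alone (adjusted p = 0.0674 with an estimated correlation). Of 24 cholesterol biosynthesis genes 2 fell, 4 when adjusted over the list alone (adjusted p = 0.242 with an estimated correlation). By camera the inflammasome list did not pass without control 3, control 4, oxLDL 1 or oxLDL 3 (0.113, 0.0589, 0.0728 and 0.0684), the p53 list without control 3 or oxLDL 2 (0.079 and 0.0741), and the cholesterol list without control 3, control 4 or oxLDL 1 (0.105, 0.115 and 0.0809). In the combination against control the p53 list, 1 higher and 3 lower of 24 by either count, and the inflammasome list, 4 higher of 14 and 5 when adjusted over the list alone, also passed with an estimated correlation (adjusted p = 0.031 and 0.0416).

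Of 16 matrix metalloproteinase and plaque remodelling genes 6 rose and 3 fell with oxLDL, 6 and 4 when adjusted over the list alone. Their median log2 change was 0.09, their mean -0.03 and the direction of the test upward (adjusted p = 0.166 by camera), and Mmp9, a matrix protease, fell by 0.52. Mitochondrial transcripts made up 9.35 ± 1.33% of counts in control, 8.57 ± 0.705% with oxLDL, 8.44 ± 0.27% with tirzepatide and 9.09 ± 1.1% with both (SD, n = 4). The exact permutation p was 0.371 for oxLDL and 0.286 for tirzepatide against control and 0.457 for the combination against oxLDL, two-sided, and 0.0286 is the smallest this design allows. Compared by library number, a check chosen after the values were seen, oxLDL lay below control in 3, tirzepatide below control in 4 and the combination below oxLDL in 1 of the 4 numbers, where sign flips cannot give a p under 0.125.

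Txnip, Arrdc4 and Klf10, which rose with tirzepatide in the absence and presence of oxLDL, are known targets of the glucose sensors MondoA and ChREBP, so a glucose-sensing response could be at work. Of the 8 further tested genes of the list written for this, the sensors and their partner left out after the result was seen, 1 was called higher with tirzepatide, Klf11 at 0.33 (SE 0.07), and 3 had a positive sign. These counts argue against a response shared by most of the 8 genes. Whether the 8 genes follow the sensors in these cells was not tested, so a response limited to fewer targets stays open. Klf11 beside oxLDL had 0.20 (SE 0.07, adjusted p = 0.358 by edgeR).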
